A study of Caenorhabditis elegans with 15 samples.

How the data were processed

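RNA was taken from whole Caenorhabditis elegans of 3 strains, grown for 3 days at 20 °C per the labels' protocols. Strain KX155 carries both eIF4E paralogs with N-terminal tags placed at the native loci, mKate on IFE-1 and GFP on IFE-3. From frozen, crushed worms of this strain, mKate::IFE-1 was bound to RFP trap beads, GFP::IFE-3 was bound to GFP trap beads, and total RNA was taken from the unenriched homogenate. Such a pull-down followed by sequencing of the bound RNA is called RIP-seq. Strains LP307 (mKate::PH) and LP306 (GFP::PH) express a tag without an eIF4E, and their RNA was taken from the RFP trap and the GFP trap, respectively. The 15 libraries form 5 groups of 3, and the labels call the replicates biological. Libraries were depleted of rRNA and were not strand-specific, per the labels' protocols, so reads of overlapping sense and antisense genes could not be separated.

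The authors deposited a single table of TPM values per gene, a length-normalised abundance with a fixed sum per library, for all libraries. The submitters' processing notes name kallisto 0.48.0, DESeq2 1.34.0, R 4.4.1 and the genome build WBcel235, with no role or order. The transcript annotation, read filters and the way transcripts were summed to genes are not given in the sources used here. TPM divides by transcript length and fixes the sum of each library, so it keeps no sequencing depth and no amount of RNA recovered. Depth is therefore unknown, no counting interval or detection floor could be given, and no count-based test was run. A rise of a few very abundant RNAs lowers the TPM of all others in the same library. The series design states that the control RIPs were left out of the submitters' analysis because mRNA was poorly represented in them. They were kept here as background, and their TPM values do not show how much RNA the control beads held.

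The table lists 46934 gene IDs, of which 19785 were at 0 in all libraries and 14844 were above 0 in all. Values were identical in every library for 152 genes in 63 sets, the largest with 11 genes, and the value of each such gene is uncertain because reads of near-identical copies cannot be assigned. The table names genes by WormBase IDs only. None could be named from the gene table used here, in which 0 IDs matched among 46926 genes, so gene symbols, classes and positions are not given. The gene lists and cell type markers fixed before the data were examined, the tests of these lists, the always-named genes and a rescaling over protein-coding genes all need symbols or classes and could not be applied. For the same reason the tagged genes themselves could not be checked.

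Each library was divided by the median, over genes above 0 in every library of a fit, of the ratio to the gene's geometric mean. Genes with at least 1 TPM in at least 3 libraries of the fit were tested on log2(scaled TPM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(scaled TPM + 1) scale, which understates the change of low genes. IFE-1 RIP, IFE-3 RIP and total RNA were compared in a single fit of 9 libraries, which shares a single estimate of the spread. Each RIP was compared with its own control RIP in a fit of 6 libraries. Medians of gene sets over total RNA, and the values given for single genes, used factors computed over all 15 libraries.

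The rule for the genes to be named required a gene-class symbol and could not be applied as written. Its remaining parts were kept: an adjusted p under 0.05, groups that do not overlap, a mean of at least 10 scaled TPM in the higher group and the largest fold change. At most 2 IDs in each direction were taken for each of the 3 comparisons within strain KX155.

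Replicate numbers are shared by all groups. Whether they pair the libraries was checked before any blocked fit was compared, by correlating the deviations from the group means over genes. For same-numbered libraries the correlations were 0.224, 0.149 and 0.396 between IFE-1 RIP and IFE-3 RIP, 0.168, 0.152 and 0.353 between IFE-1 RIP and mKate control RIP, and 0.191, 0.173 and 0.273 between IFE-3 RIP and GFP control RIP. Libraries of unlike number correlated by at most 0.107, 0.133 and 0.0862, in the same order. The numbers were taken to pair the libraries in these 3 comparisons, a pairing that comes from the data and not from the labels. The main counts, named genes and gene sets still come from the fits without a block, set before the data were seen. Those fits ignore the pairing, and counts with a block are given beside them. The batch named in the labels (RFP pulldown, GFP pulldown or lysate) coincides with the group in every comparison except between a RIP and its own control, which share a batch. For the other comparisons batch and group cannot be told apart.

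The number of genes with at least 1 TPM and the share of TPM in the 10 highest genes were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. For the overlap of genes called against the shared total RNA libraries, unchanged groups were simulated 100 times. The limma procedure was tested on simulated data with 200 genes changed among those tested. A log2 change of 1 was recovered for 64% of the changed genes in IFE-1 RIP against total RNA, 68% in IFE-3 RIP against total RNA and 61% between the RIPs. Recovery was 50% against the mKate control RIP and 14% against the GFP control RIP. A log2 change of 2 was recovered for 91%, 83%, 89%, 74% and 64%, in the same order. False calls were 10 of 165, 8 of 159, 7 of 157, 15 of 139 and 2 of 80 calls, also in that order. The simulated libraries shared no variation by replicate number. Each simulated gene also had the same spread in every group, unlike the data, so false calls under unequal spread were not measured. Alternatives covered the scaling, the pseudocount, the filter on low values, the variance model, library weights, the replicate block, the libraries in the fit, a fold minimum, genes with identical values and each library left out in turn.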

Results

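The eIF4E proteins bind the 5' cap of mRNAs, and IFE-1 and IFE-3 are paralogs of this cap-binding family in C. elegans. To determine which RNAs each paralog held, RIP-seq was performed for both from the same worm strain, KX155, in which IFE-1 carried mKate and IFE-3 carried GFP. The RNA bound to mKate::IFE-1 (IFE-1 RIP), the RNA bound to GFP::IFE-3 (IFE-3 RIP) and total RNA were measured in 3 libraries each. Strains that expressed only tagged PH gave 3 mKate control RIP and 3 GFP control RIP libraries. Values are TPM, the depth of the libraries is unknown, and genes are given by their WormBase IDs because no symbols were paired with them.

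Many RNAs were detected in every group, the control RIPs included. At least 1 TPM was reached by 11978 ± 591 genes in IFE-1 RIP, 11541 ± 472 in IFE-3 RIP and 10420 ± 313 in total RNA (SD, n = 3 each). The control RIPs were not lower in this measure, with 12472 ± 300 genes in mKate control RIP and 13024 ± 1138 in GFP control RIP (SD, n = 3 each). Few genes took most of the TPM. The 10 highest genes held 67.9 ± 4.74% of the TPM in IFE-1 RIP, 63.7 ± 2.04% in IFE-3 RIP, 75.4 ± 0.510% in total RNA, 73.4 ± 2.05% in mKate control RIP and 65.8 ± 7.19% in GFP control RIP (SD, n = 3 each). All IFE RIP libraries had more genes at 1 TPM and a lower share in the 10 highest genes than all total RNA libraries, which gave an exact permutation p of 0.1, the smallest possible, and an adjusted p of 0.2 over 10 such tests by the same exact permutation. Between the IFE RIPs the exact permutation p was 0.4 for the number of genes and 0.3 for the share.

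**Figure D1:**
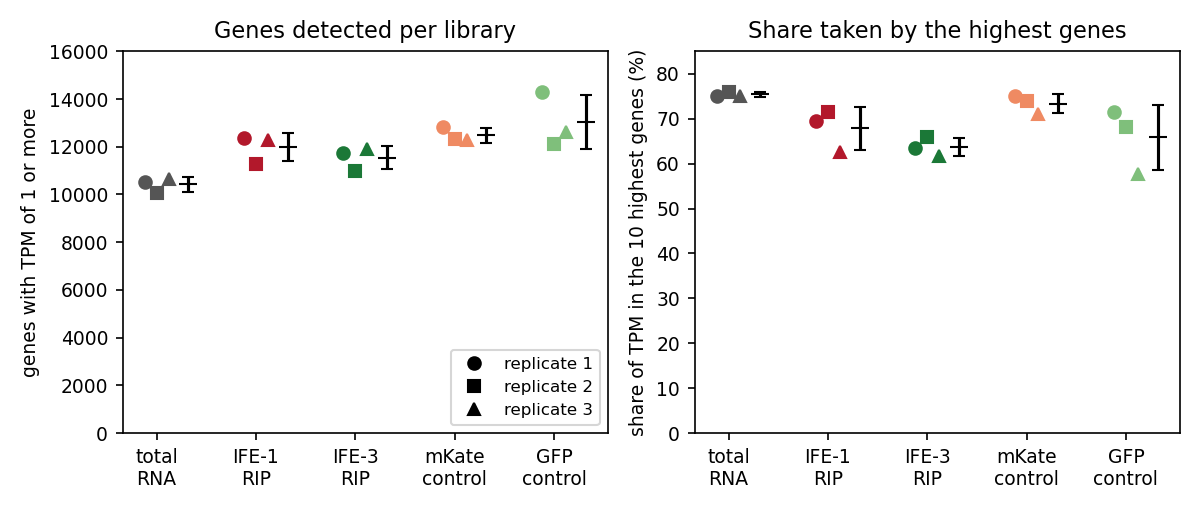
Number of genes with at least 1 TPM (left) and percent of TPM in the 10 highest genes (right) for each of the 15 libraries, by group, with symbols for the replicates and a bar for the mean ± SD of each group. Total RNA had the fewest genes (10420 ± 313) and the highest share in its 10 highest genes (75.4 ± 0.510%).

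Over 14308 genes, libraries of the same group ranked genes most alike in total RNA, with a median Spearman rho across genes of 0.930, and least alike in GFP control RIP, with 0.821. The median was 0.906 within IFE-1 RIP, 0.924 within IFE-3 RIP and 0.900 within mKate control RIP. Between IFE-1 RIP and IFE-3 RIP it was 0.909, and between these and total RNA it was 0.897 and 0.911, respectively. Genes are not independent replicates, and these values describe the libraries only.

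To find the RNAs held by IFE-1, its RIP was compared with total RNA. Of 12099 genes tested, 498 were higher in IFE-1 RIP and 734 were lower. The median log2 fold change was 0.93 for the higher genes and -0.56 for the lower ones, and 221 genes were at least 2-fold higher against 32 at least 2-fold lower. Of the higher genes, 48 were listed at 0 in all total RNA libraries, and the median of the others was 0.87. WBGene00045160 stood at 320, 177 and 61.1 scaled TPM in IFE-1 RIP replicates 1, 2 and 3 and at 0, 12.4 and 18.3 in those of total RNA (log2 fold change 4.52 ± 1.01 SE, limma adjusted p = 0.0255). WBGene00044974 stood at 170, 78.0 and 154 in IFE-1 RIP and at 8.01, 0 and 38.7 in total RNA (log2 fold change 4.11 ± 1.05 SE, limma adjusted p = 0.0419). In the mKate control RIP the same genes stood at 85.4, 0 and 0, and at 70.5, 30.0 and 52.4. The largest decrease among the named genes was that of WBGene00014621, from 1017 ± 431 scaled TPM in total RNA to 101 ± 83.5 in IFE-1 RIP (SD, n = 3 each, log2 fold change -3.54 ± 0.81 SE, limma adjusted p = 0.0276). It belongs to a set of 11 genes with identical values, and it stood at 37.1 ± 29.2 in mKate control RIP (SD, n = 3). WBGene00045168 was at 8084 ± 2275 in total RNA, 2385 ± 1463 in IFE-1 RIP and 1978 ± 505 in mKate control RIP (SD, n = 3 each), with a log2 fold change of -1.89 ± 0.44 SE against total RNA (limma adjusted p = 0.0283).

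Calls of this comparison made up 1232 genes with limma, and 3197 genes had an unadjusted p under 0.05. In each called gene the libraries of both groups did not overlap, as was the case for 32.7% of all genes tested against 10% given by chance. With TPM as deposited, which moved the median of all genes to 0.21 on the log2 scale, 1133 genes were higher and 153 lower, so 88.1% of the calls were higher against 40.4% with scaled libraries. The count was 777, 769 and 737 without IFE-1 RIP replicates 1, 2 and 3, 517 and 619 without total RNA replicates 1 and 2, 1892 with library weights and 235 with all 15 libraries in a single fit. Of 21 other fits, the calls of WBGene00045160, WBGene00044974, WBGene00014621 and WBGene00045168 were lost in 7, 10, 6 and 8.

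The same comparison was made for IFE-3. Of 12099 genes tested, 675 were higher in IFE-3 RIP than in total RNA and 681 were lower, with a median log2 fold change of 0.82 and -0.54, respectively. At least 2-fold differences were found for 218 higher and 43 lower genes, and 38 of the higher genes were listed at 0 in all total RNA libraries (median of the others 0.79). WBGene00045160 stood at 250, 314 and 212 scaled TPM in IFE-3 RIP replicates 1, 2 and 3 (log2 fold change 5.28 ± 1.01 SE, limma adjusted p = 0.0161), and it was listed at 0 in all 3 GFP control RIP libraries. WBGene00044974 stood at 117 ± 25.6 in IFE-3 RIP (SD, n = 3, log2 fold change 3.98 ± 1.05 SE, limma adjusted p = 0.0448) and at 37.5 ± 18.2 in GFP control RIP (SD, n = 3). WBGene00014621 was lower also in this RIP, at 98.9 ± 88.9 scaled TPM (SD, n = 3, log2 fold change -3.78 ± 0.81 SE, limma adjusted p = 0.0230), and stood at 15.5 ± 7.92 in GFP control RIP (SD, n = 3). WBGene00045117 was at 26.3 ± 4.15 in total RNA and 3.10 ± 2.40 in IFE-3 RIP (SD, n = 3 each, log2 fold change -2.82 ± 0.68 SE, limma adjusted p = 0.0339), and it was listed at 0 in all 3 GFP control RIP libraries.

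In total 1356 genes were called with limma for IFE-3 RIP against total RNA, and 3256 had an unadjusted p under 0.05. Groups did not overlap in 31.3% of the genes tested, against 10% given by chance. With TPM as deposited, which moved the median of all genes to 0.27, 2599 genes were higher and 159 lower, so 94.2% of 2758 calls were higher against 49.8% with scaled libraries. The count was 690 and 320 without IFE-3 RIP replicates 1 and 2, 386, 423 and 613 without total RNA replicates 1, 2 and 3, 4523 with library weights, 253 with all 15 libraries in a single fit and 717 without a filter on low values. The calls of WBGene00045160, WBGene00044974, WBGene00014621 and WBGene00045117 were lost in 2, 12, 6 and 8 of 21 other fits, so that of WBGene00044974 was lost in most.

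To determine how far the RNAs of the paralogs coincided, the genes called against total RNA were compared. In both RIPs 258 genes were higher and 468 were lower, and 0 genes went in opposite directions. Independent lists of these lengths would share 27.8 higher and 41.3 lower genes, and unchanged groups set against the same total RNA libraries shared a mean of 0.03 and 0. Unchanged groups yield few calls at all, so the simulated overlap does not set a level for lists of this length. The 3 total RNA libraries could not be divided into parts of sufficient size, so part of the excess of common genes over independent lists may come from these shared libraries. Across genes the fold changes of the RIPs correlated with a Pearson r of 0.710, against a mean of 0.499 in the simulation. Their covariance was 0.179 against 0.0490, a difference of 0.130. The simulation held no variation common to IFE-1 RIP and IFE-3 RIP libraries of the same number, which may raise both values in the data. The genes higher in both RIPs held 6.70 ± 1.33% of the TPM in IFE-1 RIP and 5.67 ± 0.102% in IFE-3 RIP, against 1.65 ± 0.102% in total RNA, 4.23 ± 0.323% in mKate control RIP and 4.10 ± 0.848% in GFP control RIP (SD, n = 3 each). Their median log2 ratio to total RNA was 1.04 in IFE-1 RIP and 0.90 in IFE-3 RIP. It was 0.38 in mKate control RIP and 0.69 in GFP control RIP, so the controls lay above total RNA too. The same total RNA libraries picked the genes and serve as the reference, which raises these values in every group.

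A further 240 genes were called higher only in IFE-1 RIP and 417 only in IFE-3 RIP. When the RIPs were tested against each other, 12 of the 240 were called higher in IFE-1 RIP, 128 of the 417 were called higher in IFE-3 RIP, and 0 of the 258 common genes were called, while 39 of them had an unadjusted p under 0.05. With the replicate number as a block 5 of the 258 were called, all higher in IFE-1 RIP, with a log2 fold change between the RIPs from 0.42 to 1.03. The count of common higher genes was 846 with TPM as deposited, 596 with library weights, 126 without a filter on low values and 52 with all 15 libraries in a single fit. It was 85 without IFE-3 RIP replicate 2, and 100, 129 and 133 without total RNA replicates 1, 2 and 3.

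**Figure D2:**
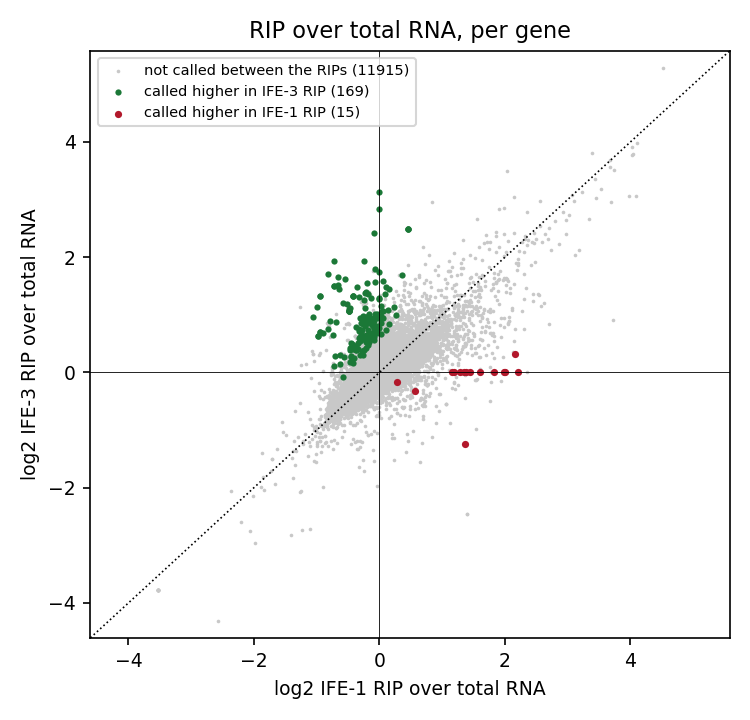
Log2 fold change over total RNA in IFE-1 RIP (horizontal) and in IFE-3 RIP (vertical) for 12099 genes, each a point, with equal change on the dotted line. Green points are the 169 genes called higher in IFE-3 RIP than in IFE-1 RIP, and red points are the 15 called higher in IFE-1 RIP, of which 12 were listed at 0 in all IFE-3 RIP libraries.

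To determine which RNAs separated the paralogs, IFE-1 RIP was compared directly with IFE-3 RIP. Of 12099 genes, 169 were higher in IFE-3 RIP, with a median log2 IFE-1 RIP over IFE-3 RIP of -1.02, and 15 were higher in IFE-1 RIP. The 169 genes held 9.40 ± 2.39% of the TPM in IFE-3 RIP and 2.28 ± 0.701% in IFE-1 RIP, while they held 2.84 ± 0.209% in total RNA, 1.65 ± 0.432% in mKate control RIP and 3.10 ± 1.60% in GFP control RIP (SD, n = 3 each). Of these genes 128 were also called higher in IFE-3 RIP than in total RNA, 7 were called lower in IFE-1 RIP than in total RNA, and 34 were called in neither way. Among the 472 genes with a mean of at least 100 scaled TPM, 42 (8.90%) were higher in IFE-3 RIP and 0 were higher in IFE-1 RIP. WBGene00001941 stood at 4774 ± 1553 scaled TPM in IFE-3 RIP, 756 ± 233 in IFE-1 RIP and 1203 ± 44.3 in total RNA (SD, n = 3 each). Its log2 fold change between the RIPs was -2.66 ± 0.29 SE (limma adjusted p = 0.0156). WBGene00001933 stood at 4241 ± 1242 in IFE-3 RIP, 750 ± 236 in IFE-1 RIP and 1270 ± 25.9 in total RNA (SD, n = 3 each), with a log2 fold change of -2.52 ± 0.28 SE (limma adjusted p = 0.0156). In GFP control RIP these genes were at 766 ± 530 and 703 ± 419, and in mKate control RIP at 369 ± 133 and 510 ± 171 (SD, n = 3 each).

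The genes on the IFE-1 side were of low abundance. Of the 15, 12 were listed at 0 in all IFE-3 RIP libraries, and 12 had a mean under 2 scaled TPM. Only WBGene00013200 met the level set for naming, at 35.1 ± 0.968 scaled TPM in IFE-1 RIP, 25.0 ± 0.852 in IFE-3 RIP and 28.6 ± 1.28 in total RNA (SD, n = 3 each, log2 fold change 0.46 ± 0.08 SE, limma adjusted p = 0.0442). It stood at 20.6 ± 3.27 in mKate control RIP and 33.3 ± 12.2 in GFP control RIP (SD, n = 3 each). The 15 genes held 0.00734 ± 0.00102% of the TPM in IFE-1 RIP, 0.00268 ± 0.000242% in IFE-3 RIP and 0.00257 ± 0.000146% in total RNA, against 0.00363 ± 0.000126% in mKate control RIP and 0.00743 ± 0.00316% in GFP control RIP (SD, n = 3 each), and 13 of them lay above total RNA in GFP control RIP.

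Between the RIPs 184 genes were called with limma and 2010 genes were found with an unadjusted p under 0.05, and groups did not overlap in 20.6% of the genes tested against 10% given by chance. With the replicate number as a block 532 genes were called, 491 of them higher in IFE-3 RIP, and 181 of the 184 were among them. The count rested on the libraries in the fit: it was 2 when the 6 RIP libraries were fitted alone and 0 with a block in that fit (2928 with an unadjusted p under 0.05), 30 with all 15 libraries, 2127 with library weights, 96 without the mean-variance trend, 105 with a pseudocount of 5, 389 with a filter at 5 TPM and 23 without a filter. It was 4, 2 and 31 without IFE-1 RIP replicates 1, 2 and 3, and 7, 5 and 897 without IFE-3 RIP replicates 1, 2 and 3. The calls of WBGene00001941, WBGene00001933 and WBGene00013200 were lost in 6, 5 and 11 of 21 other fits. Over all 3 comparisons within the strain, calls of the genes named by ID were counted over combinations of gene and fit. With a library left out they held in 22 combinations and were lost in 44, with no change of sign. The naming rule took only genes whose groups do not overlap, so leaving a library out could hardly turn a sign.

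The composition of the RNA held by each trap, though not its amount, was measured in the strains with a tag alone. Against mKate control RIP, 38 genes were higher in IFE-1 RIP and 20 were lower among 12238 tested. Of 497 genes called higher in IFE-1 RIP than in total RNA and tested here, 90.9% lay above mKate control RIP, with a median log2 ratio of 0.71, while 50.7% of all genes did. Only 6 of the 497 were called, where 1.63 would be shared by independent lists. With the replicate number as a block 1554 genes were called, 1046 of them higher, and 210 of the 497 were among the higher ones, against 44.9 for independent lists. These lists share the IFE-1 RIP libraries, so part of the excess may come from them. Without the block 58 genes were called with limma and 3357 had an unadjusted p under 0.05. With limma the count was 1, 0 and 0 without IFE-1 RIP replicates 1, 2 and 3, 0, 1 and 1486 without mKate control RIP replicates 1, 2 and 3, 0 without a filter on low values (4083 with an unadjusted p under 0.05), 343 with a filter at 5 TPM, 97 after quantile normalization, 36 with a pseudocount of 5, 161 with all 15 libraries and 2996 with library weights. Where a library left out gave 0, between 2201 and 2440 genes had an unadjusted p under 0.05. With TPM as deposited, which moved the median of all genes to -0.20, 18 genes were higher and 23 lower.

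Against GFP control RIP, 8 genes were higher in IFE-3 RIP and 3 were lower among 12249 tested. Of 674 genes called higher in IFE-3 RIP than in total RNA and tested here, 86.1% lay above GFP control RIP, with a median log2 ratio of 0.60, while 52.0% of all genes did. Of the 674, 5 were called, where 0.466 would be shared by independent lists. With the replicate number as a block 141 genes were called, 73 of them higher, and 28 of the 674 were among the higher ones, against 4.25 for independent lists. The lists compared share the IFE-3 RIP libraries, so part of the excess may come from these libraries. Without the block 11 genes were called with limma and 1534 had an unadjusted p under 0.05. With limma the count was 0 without IFE-3 RIP replicates 1, 2 and 3 in turn (908, 878 and 1267 genes with an unadjusted p under 0.05), 2, 258 and 1 without GFP control RIP replicates 1, 2 and 3, 1 without a filter on low values, 23 with a filter at 5 TPM, 27 without the mean-variance trend, 3 after quantile normalization, 3 with a pseudocount of 0.1, 618 with all 15 libraries and 497 with library weights. With TPM as deposited, which moved the median of all genes to -0.29, 2 genes were higher and 2 lower.

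**Figure D3:**
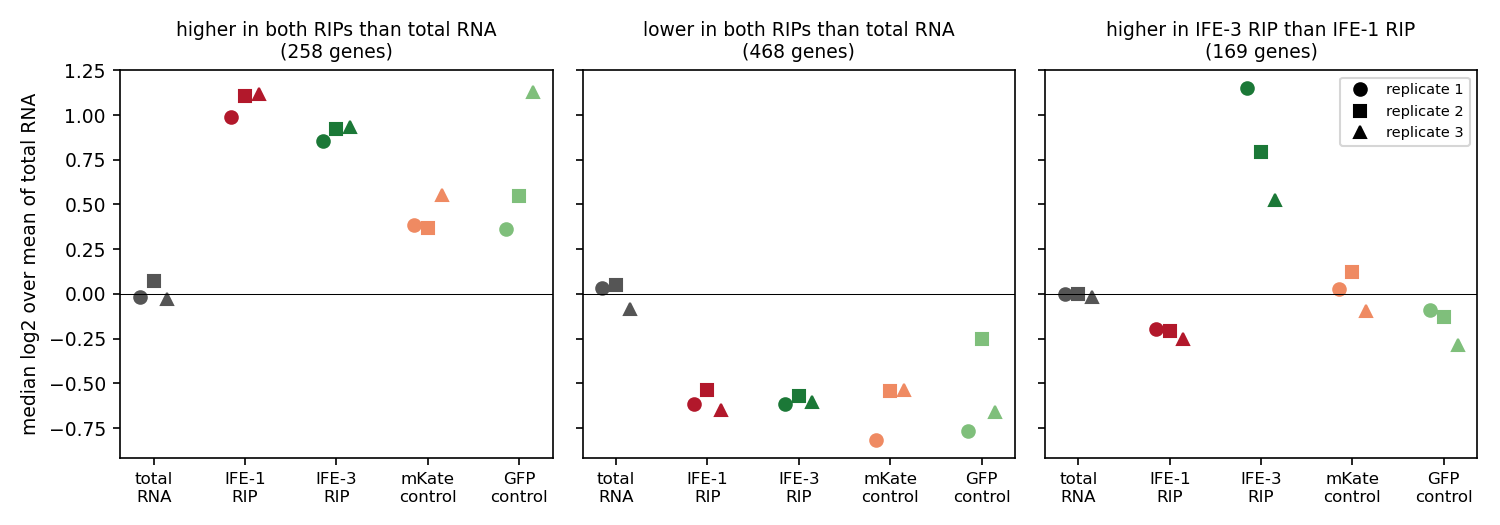
Median log2 ratio to the mean of total RNA in each of the 15 libraries, by group and replicate, over the 258 genes higher in both RIPs (left), the 468 genes lower in both (middle) and the 169 genes higher in IFE-3 RIP than in IFE-1 RIP (right). The genes lower in both RIPs lay between -0.82 and -0.54 in mKate control RIP and between -0.77 and -0.25 in GFP control RIP, while the 169 genes lay between 0.53 and 1.15 in IFE-3 RIP and between -0.25 and -0.20 in IFE-1 RIP.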

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

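The comparison with the control traps, the bounds for the counts across scalings, the count with identical genes taken once and the test of the control-corrected difference were chosen after the data were seen. The direct comparison, the scalings, the fit of its 6 libraries alone, the libraries left out in turn and the divisions of the libraries were set before.

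The ratio of RIP to total RNA differed between the paralogs for 184 of 12099 genes (limma, Benjamini-Hochberg adjusted), 169 higher in IFE-3 RIP and 15 higher in IFE-1 RIP. Since the total RNA libraries are common to both ratios, this test is the direct comparison of the RIPs. If the GFP trap or its tag held these RNAs without IFE-3, GFP control RIP should exceed mKate control RIP by most of the difference. Its median log2 excess over the 169 genes was -0.251 of the median difference between the RIPs, and between -0.330 and -0.130 with each control library left out. That result covers the median gene only. By share of TPM the 169 genes stood higher in GFP control RIP (3.10 ± 1.60%) than in mKate control RIP (1.65 ± 0.432%, SD, n = 3 each). In replicates 1, 2 and 3 they held 1.90, 2.47 and 4.92% in GFP control RIP and 11.7, 9.58 and 6.92% in IFE-3 RIP. Trap RNA as a part therefore stays open for the most abundant of these genes. With genes of identical values counted once 147 genes were called on the IFE-3 side, and other scalings called 145 and 190. So neither counting such genes separately nor the scaling accounts for most of the count. Of 123 tested genes with identical values, 18 were among the 169. Reads shared among copies whose values differ were not examined. Of the 10 divisions of the 6 RIP libraries into groups of 3, only the real one called 184 genes and the highest other called 7. However, 10 divisions are too few for a share under 0.05. The other divisions mix the paralogs, so a real difference adds to their spread and 7 is no level for unchanged groups. The count was 2 when the 6 libraries were fitted alone and ranged from 2 to 897 with single libraries left out. A preference of IFE-3 over IFE-1 for these RNAs may underlie the difference, as a hypothesis, and it cannot be told apart from other differences between the GFP and RFP pulldowns, such as the amount of each paralog bound, which coincide with the paralog.

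When each RIP was first set against its own control RIP, in a fit of 12 libraries, the ratio differed between the paralogs for 45 of 14114 genes with limma, 13 on the IFE-3 side and 32 on the IFE-1 side, and 2375 genes had an unadjusted p under 0.05. Of the 169 genes, 9 were called. Their sign was the same for 95.9%, against 73.9% of the 12049 genes tested in both, but both tests use the same RIP libraries, so such agreement is largely built in. With the replicate number as a block 923 genes were called, 602 on the IFE-3 side and 321 on the IFE-1 side, so the split turned, and 112 of the 169 were among those on the IFE-3 side.

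Of the genes named by ID, WBGene00001941 and WBGene00001933 differed between the paralogs by a log2 IFE-1 RIP over IFE-3 RIP of -2.66 and -2.52, and WBGene00013200 by 0.46. Their calls were lost in 6, 5 and 11 of 21 other fits, respectively, among them the fit of the 6 RIP libraries alone (limma adjusted p = 0.154, 0.154 and 0.162) and that fit with a block (limma adjusted p = 0.0893 for each).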

How the results depend on the processing

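Counting genes of identical values once, the filter at a mean of 10 TPM and the block within 6 libraries were chosen after seeing the data, and the other alternatives before. No gene named by ID changed sign under any alternative run, but the split of higher and lower calls turned with the scaling and with other settings. With TPM as deposited it went from 498 and 734 to 1133 and 153 for IFE-1 RIP against total RNA, from 675 and 681 to 2599 and 159 for IFE-3 RIP against total RNA, and from 38 and 20 to 18 and 23 against mKate control RIP. For IFE-1 RIP against total RNA it was 320 and 299 without total RNA replicate 2 and 221 and 32 with a fold of at least 2. The near-even split of IFE-3 RIP against total RNA became 218 and 43 with that fold, 1014 and 600 without IFE-3 RIP replicate 3, 2478 and 2045 with library weights and 1126 and 1047 with the replicate block, while it was 638 and 937 after quantile normalization and 283 and 434 without a filter. Where counts moved by over 1.5 times, the cause was not tested, unless fewer genes or libraries in a fit account for it.

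Counts are given in the order IFE-1 RIP against total RNA, IFE-3 RIP against total RNA, the direct comparison, IFE-1 RIP against mKate control RIP, IFE-3 RIP against GFP control RIP and genes higher in both RIPs, for which the values reported were 1232, 1356, 184, 58, 11 and 258. With library weights they were 1892, 4523, 2127, 2996, 497 and 596, and some of these weights did not converge. A single fit of 15 libraries gave 235, 253, 30, 161, 618 and 52. A fold of at least 2 gave 253 and 261 against total RNA, 98 in the direct comparison, and held for 40.3% of the 258 genes higher in both RIPs. TPM as deposited gave 2758 for IFE-3 RIP against total RNA, 4 against GFP control RIP and 846 in both RIPs, with shifts of all genes as given with each comparison. Quantile normalization gave 97 against mKate control RIP and 3 against GFP control RIP. Without a filter the counts were 717 for IFE-3 RIP against total RNA, 23 in the direct comparison, 0 and 1 against the controls and 126 in both RIPs. The 0 came from limma with 4083 genes at an unadjusted p under 0.05. A filter at 5 TPM gave 389, 343 and 23 in the direct comparison and against the mKate and GFP controls. A pseudocount of 5 gave 105 in the direct comparison and 36 against mKate control RIP, and a pseudocount of 0.1 gave 3 against GFP control RIP. Without the mean-variance trend 96 genes were called in the direct comparison and 27 against GFP control RIP.

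With the replicate block the counts were 2053, 2173, 532, 1554, 141 and 426. Same-numbered libraries of the RIPs and total RNA correlated by 0.0346, 0.0791 and 0.154 for IFE-1 and by 0.0552, 0.130 and 0.0981 for IFE-3, not all above 0.1, so these libraries were not treated as paired. Each library correlated best with its own number for IFE-3 and not for IFE-1, so a pairing with total RNA is not excluded. In the 6 libraries of the groups compared, without a block, the direct comparison called 2 genes. With a replicate block in such a fit it called 0 (limma, with 2928 genes at an unadjusted p under 0.05), and IFE-3 RIP against total RNA called 502. The median SD over genes was 0.149 in total RNA, 0.188 in IFE-1 RIP and 0.203 in IFE-3 RIP, so the fit of 9 libraries takes part of its spread from the less variable total RNA.

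Without single libraries the counts ranged from 517 (without total RNA replicate 1) to 866, from 320 (without IFE-3 RIP replicate 2) to 1614, from 2 (without IFE-1 RIP replicate 2) to 897 (without IFE-3 RIP replicate 3), from 0 to 1486 (without mKate control RIP replicate 3), from 0 to 258 (without GFP control RIP replicate 2) and from 85 to 224, in the same order. In each such fit a group of 2 libraries remained.

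The IFE RIPs had 1340 more genes at 1 TPM than total RNA, between 1163 and 1491 with single libraries left out. The share of the 10 highest genes was -9.65 percentage points from that of total RNA, between -10.8 and -8.86 with single libraries left out, and that of the 50 highest was -5.85. The named genes kept their sign in every fit: their calls held in 22 fits and were lost in 44 with a library left out, and held in 128 and were lost in 37 under other alternatives.

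The rescaling over protein-coding genes, the tests of gene lists and their alternatives were not run, because the IDs could not be given symbols or classes. Depth is unknown, so its effect on low genes could not be measured.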

Other observations

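The tests of loss in the traps, of the control traps or the paralogs as the whole cause and of the spread of the control libraries, and the calls in 2 replicates measured in the one left out, were chosen after the results were seen. The test of RNA held by the traps and the divisions of the libraries were set before.

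The calls were not spread evenly over abundance. Among the 472 genes with a mean of at least 100 scaled TPM, 18.9% were higher and 12.7% lower in IFE-1 RIP than in total RNA, and 19.3% were higher and 15.0% lower in IFE-3 RIP. Among the 3339 genes under 2 scaled TPM these shares were 2.07% and 0.150% for IFE-1 RIP and 1.50% and 0.569% for IFE-3 RIP. Lower genes of at least 100 scaled TPM had a median log2 fold change of -0.80 and -0.78, respectively.

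When genes were called in 2 replicates and measured in the one left out, the number of genes depended on that replicate. For IFE-1 RIP against total RNA, 64, 124 and 130 higher genes were called with replicates 1, 2 and 3 left out, with medians of 1.41, 1.08 and 1.17 on the log2 scale in the replicate left out, and 12, 66 and 150 lower genes had medians of -1.07, -0.80 and -0.69. For IFE-3 RIP against total RNA, 23, 28 and 445 higher genes had medians of 1.99, 2.05 and 0.53, and 2, 2 and 313 lower genes had medians of -1.36, -1.43 and -0.55. The direction was the same for between 89.3% and 100% of the genes of these lists. For the direct comparison 1, 1 and 347 genes were called on the IFE-3 side, with medians of -2.73, -2.28 and -0.59, and 0, 0 and 8 on the IFE-1 side.

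The genes called higher in a RIP than in total RNA had a median log2 ratio to the control RIP that was 0.744 of that to total RNA for IFE-1, between 0.664 and 0.872 with each control library left out, and 0.719 for IFE-3, between 0.701 and 0.813, but the genes were picked in the same RIP libraries. In RIP libraries left out of the calls the fraction was at least 0.542 for IFE-1. On the scaled values this argues against RNA held by the RFP trap or the tag as the whole cause of these higher values. For IFE-3 the fraction was 0.717, 0.508 and 0.642 with RIP replicates 1, 2 and 3 left out. It was between 0.374 and 0.748 with control libraries left out too. All lie above the 0.25 under which trap RNA as the whole cause was to lie, but not all above the 0.5 set against it. Over all 675 genes trap RNA as the whole cause therefore cannot be told apart from binding to IFE-3. For the 128 of them also higher than in IFE-1 RIP, the median log2 ratio of GFP control RIP to total RNA was between -0.282 and -0.00868 of that of IFE-3 RIP. On the scaled values this argues against trap RNA as the whole cause for these 128 genes. They were picked in the same IFE-3 RIP libraries, though, and no library was left out. RNA held by the trap as a part of the higher values stays open for both. The fractions lie on both sides of the bound of 0.75. All total RNA libraries took part in the calls and served as the reference, which lowers these fractions. The control strains also differ from KX155 in more than the paralog, and TPM shows no amount of RNA. These answers take the median gene as unchanged. The scaling factors were 0.713 to 0.818 in total RNA, 0.875 to 1.04 in the IFE RIPs and 1.05 to 1.36 in the control RIPs. The larger factors lower the control RIPs against total RNA. The fractions were not computed with TPM as deposited, so the answers hold for scaled libraries only.

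Over the 734 genes lower in IFE-1 RIP and the 681 lower in IFE-3 RIP, the median log2 ratio of the control RIP to total RNA was 0.908 and 0.879 of that of the IFE RIP, but the same total RNA libraries picked the genes and serve as the reference, which raises these fractions. Against total RNA libraries left out of the calls, the fraction had a median of 0.899 for IFE-1, between 0.746 and 0.987 with control libraries left out, and 0.849 for IFE-3, between 0.661 and 1.15. On the scaled values these fractions argue against a loss that needs the paralog as the whole cause, which was to give fractions under 0.25. The control strains differ from KX155 in more than the paralog, though, and the scaling lowers the control RIPs against total RNA. With TPM as deposited 153 genes were lower in IFE-1 RIP and 159 in IFE-3 RIP. No fraction was computed on those values, so the answer holds for scaled libraries only. Because the ranges reach below the bound of 0.75, a loss in any pulldown as the whole cause cannot be told apart from one to which the paralog adds a part. Over the lower genes tested against the controls, the median log2 ratio of the RIP to its control RIP was -0.08 for IFE-1 and -0.08 for IFE-3, and with the replicate block 37 of 733 and 2 of 675 genes were called lower than in the control RIP and 29 and 0 higher.

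Without a block few genes were called against the control RIPs, 58 for IFE-1 and 11 for IFE-3. With the replicate number as a block 1554 and 141 were called, so the count for IFE-3 stayed low. Without mKate control RIP replicate 3 the count was 1486, and without GFP control RIP replicate 2 it was 258. Variation common to libraries of the same number therefore cannot be told apart from a single deviant control library. A larger spread between the control libraries may add to the low counts. The ratio of the median SD between control libraries to that between RIP libraries was 1.20 for IFE-1 and 1.87 for IFE-3. The first lies between the bounds set, so this part cannot be told apart from a smaller difference from the control.

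In the other comparisons each real division of 6 libraries was the only 1 of 10 to call as many genes, with 1232 against 4 in the highest other for IFE-1 RIP and total RNA, 1356 against 1 for IFE-3 RIP and total RNA, 58 against 7 for mKate control RIP and 11 against 2 for GFP control RIP. With 10 divisions no share under 0.05 can be reached. The other divisions mix the real groups, so a real difference adds to their spread and their counts are no level for unchanged groups.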
